A study of Mus musculus with 10 samples.

How the data were processed

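RNA was measured in IL-22-producing CD4+ T cells of 10-week-old C57BL/6 mice. Per the labels' protocols, naive splenic CD4+ T cells were activated through CD3 and CD28 and driven towards the Th22 fate with 30 ng/mL of IL-6, both IL-23 and IL-1 beta at 20 ng/mL, the aryl hydrocarbon receptor ligand FICZ at 400 nM, and blocking antibodies to IL-4 and interferon gamma. From each culture, 5000 CD4+ cells positive for a tdTomato reporter of Il22 were sorted into lysis buffer. Libraries were made by SMART-seq2, a full-length cDNA method that does not mark strand, with 10 cycles of cDNA amplification and 0.2 ng of cDNA carried into tagmentation, and were read as 38-nucleotide pairs.

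The deposited values are TPM, a length-normalized share of transcripts, which the authors obtained by aligning reads to the mm10 transcriptome with Bowtie and estimating abundance with RSEM, per the labels' protocols; the submitters' processing notes give RSEM 1.2.8 and mm10, and the Bowtie version is not given in the sources used here. TPM divides by transcript length and sets each library to a sum of 1000000, so the number of reads behind a value is unknown, no counting error can be given, and a rise in some transcripts lowers the share left for others. RSEM divides reads that match several genes between them by estimation, so values of near-identical copies are uncertain: Il22 and Iltifb, Lilrb4 and Gp49a, and the histone genes. Xist and Tsix overlap on opposite strands and cannot be told apart without strand.

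The table held 23420 rows. In 27 rows the gene symbol had been replaced by a calendar date, as spreadsheet programs do, and these rows, which held 0.107% to 0.114% of the TPM of a library, were left out of the tests. Of the 23393 remaining symbols, 23234 (99.3%) were matched to a RefSeq gene of the mm10 assembly for coordinates and 23025 (98.4%) to a GENCODE transcript for GC content and length. No column was left unused. Libraries were assigned to WT and to Riok2hKO (5 each) from their labels. The labels do not say whether libraries of a group came from separate mice or cultures, so p-values measure only the spread between these libraries, which may be technical.

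Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), on genes with at least 1 TPM in at least 5 of the 10 libraries, with a term for genotype and Benjamini-Hochberg adjustment. Adjusted p-values of single genes are from this test. Genes at an adjusted p under 0.05 are said to have changed. Log2 fold changes, and the count of genes changed at least 2-fold, are on the log2(TPM + 1) scale, which understates changes of low genes. The Riok2 percentage and the -fold changes of Il22 and Il23r are ratios of mean TPM. Riok2, Il22, Trp53 and Iltifb were also compared by two-sided exact permutation tests over all 252 assignments of the libraries, of which the smallest possible p is 0.00794. The 37 gene lists were fixed before the data were examined. The 30 lists with at least 5 tested members were compared with the other genes by camera with a preset correlation of 0.01, then by camera with a correlation estimated from the residuals and by fry, with adjustment over the lists. fry asks whether members move on balance in one direction and makes no comparison with other genes.

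On simulated data for this comparison (10335 genes, of which 200 were changed), the test found 82% of changes of 0.5 and 96% of changes of 1 on the log2 scale, and 6.67% of its calls were genes left unchanged. A shift of -0.2 given to the proteasome list was found, and 0 other lists were called. In the simulation genes varied independently of each other, which genes in these libraries do not.

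The genes named are Riok2, Il22 and Trp53, the 10 genes that rose most and the 10 that fell most among changed genes with a mean of at least 5 TPM (unnamed gene models left out), and up to 4 members of each list with the smallest p. Some genes that this rule takes are not reported here. Genes outside this rule were chosen after their values were seen: Il17a, Ifng, Ccl3, Ccl4, Asns, Ddit3, Trib3, Cdkn1a, Mdm2, Dyrk3, Ddit4, Tbx21, Cd8a, Srebf2, Gata3, Herpud1, Fbl, Cyp1a1, Gstt1, Gm10052, Pkm, Pgk1, Eno1, Aldoa, Gapdh, Ldha and those named for their level in WT replicate 1. Intervals of ratios of mean TPM come from the delta method on the log scale with Welch's degrees of freedom. Alternatives covered the pseudocount, the filter on low values, scaling (median of ratios, quantiles, and TPM recomputed without ribosomal protein genes), array weights, the variance model, the number of detected genes as a covariate, the replicate number as a block, each library left out in turn, and other list tests. Alternatives chosen after seeing the data were the sum of Il22 and Iltifb, the date rows kept in, removal of a trend on GC content and length, and removal of genes low in WT replicate 1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.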

Results

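Gene expression was compared between IL-22+ Th22 cells of wild-type mice (WT, 5 libraries) and of mice lacking 1 copy of Riok2 in blood-lineage cells through Vav1-driven Cre (Riok2hKO, 5 libraries). Riok2 encodes an atypical kinase needed for late maturation of the small ribosomal subunit. The comparison asks what the loss of 1 copy changes in the transcriptome of T cells that make IL-22. Values are TPM given as mean ± SD of the 5 libraries of a group unless stated, and sequencing depth is unknown because TPM keeps none.

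The libraries were alike in composition. Between 13948 and 14695 genes had a TPM above 0, 10269 to 10337 reached 1 TPM, the 10 most abundant transcripts held 8.92% to 9.64% of the TPM, and ribosomal protein genes held 25.4% to 26.4%. Pearson's r of log2 values across genes was 0.991 to 0.995 within WT, 0.994 to 0.996 within Riok2hKO and 0.983 to 0.993 between the groups, and no library was a duplicate of another. The first principal component held 38.9% of the variance and separated the genotypes. WT replicate 1 lay apart from the other 4 WT libraries on both components. In that library 122 genes were at least 1 log2 unit below the mean of the other WT libraries and 11 were at least 1 above. Among the low ones were Rps2 (2704 TPM against a mean of 7561), the spermidine synthase gene Srm (248 against 622), the histone-binding factor Anp32b (109 against 272) and the phosphatase Dusp2 (34.5 against 235).

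**Figure D1:**
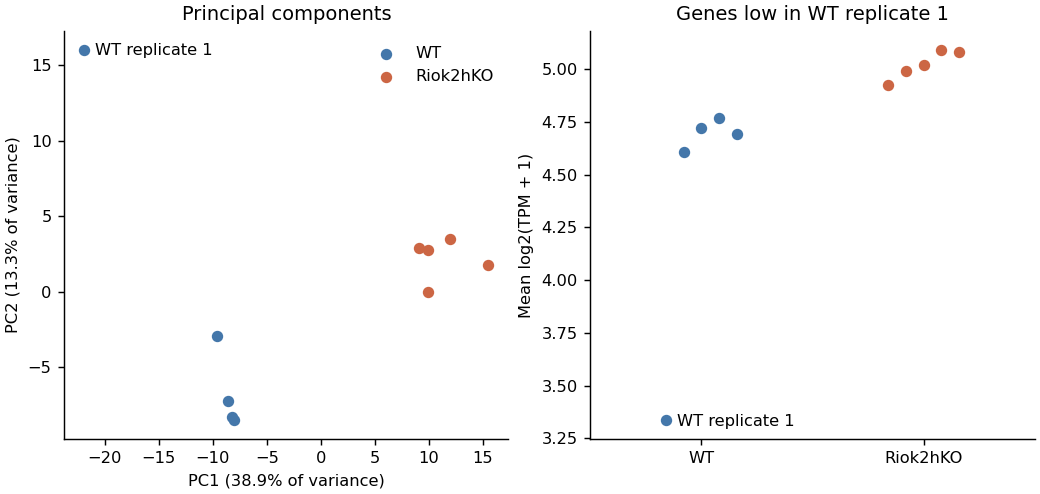
Left, the 10 libraries on the first and second principal components of log2(TPM + 1), with the share of variance of each on the axes. Right, the mean log2(TPM + 1) per library of the 122 genes lowest in WT replicate 1, which is 3.34 there, 4.61 to 4.77 in the other WT libraries and 4.93 to 5.09 in Riok2hKO; the right axis does not start at 0.

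Riok2 mRNA in Riok2hKO was 48.3% of the WT level, where the labels give a deletion of 1 copy. Riok2 (mm10 chromosome 17, 17374332 to 17394899) measured 28.3 ± 1.57 TPM in WT and 13.7 ± 1.71 in Riok2hKO, a log2 fold change of -1.01 (SE 0.0754, limma adjusted p = 7.77e-06). All 5 Riok2hKO libraries were below all 5 WT libraries (exact permutation p = 0.00794, the smallest possible). WT replicate 1 had 29.9 TPM, inside the WT range. Reads from a transcript of the deleted allele, if one is made, would count towards these values.

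Of 10332 genes tested, 1770 (17.1%) changed by limma, 990 upwards and 780 downwards in Riok2hKO. Most changes were small. The median absolute log2 fold change of the changed genes was 0.28, and 53 of them changed at least 2-fold, 48 upwards and 5 downwards. In 1507 genes (14.6%) the 2 groups did not overlap, against 0.794% by chance. Without WT replicate 1, 1749 genes changed (1028 up, 721 down), of which 1515 were among the 1770. In that fit 726 genes rose and 390 fell among the 6312 whose transcript holds a 100-nucleotide window of 70% GC or more, against 296 and 329 among the 3899 without such a window. With the number of detected genes as a covariate the count was 821. The balance of directions turned with quantile normalization (845 up, 947 down) and among genes with a mean of at least 10 TPM (680 up, 724 down).

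Genes of the cytokines IL-22, IL-24 and IL-17F and of the IL-23 receptor were among the 10 largest increases. Il22 (chromosome 10, 118204584 to 118210047) rose 5.34-fold, from 59.2 ± 12.7 to 316 ± 33.8 TPM (log2 fold change 2.42, SE 0.125, limma adjusted p = 5.78e-07; exact permutation p = 0.00794), although cells of both genotypes had been sorted as reporter-positive. Il17f (chromosome 1, 20777146 to 20785274) rose from 280 ± 29.8 to 941 ± 132 TPM, Il17a from 43.6 ± 17.2 to 129 ± 31.9, and Il24, another cytokine of the IL-10 family, from 6.40 ± 2.42 to 21.2 ± 4.26. Il23r (chromosome 6, 67422932 to 67491855), the receptor for the IL-23 in the medium, rose 5.30-fold from 2.75 ± 0.998 TPM, and Il21 went from 22.0 ± 1.80 to 43.6 ± 4.55.

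In the list of Th22 and Th17 lineage genes, 18 of 30 tested members rose, 0 fell and 12 did not pass the test (20 rose with p adjusted over the list alone). The median log2 fold change was 0.32 (camera adjusted p = 5.98e-14). This was the 1 list of the 30 whose call held with an estimated correlation (adjusted p = 0.00329). Reads of Il22 cannot be fully separated from those of Iltifb, a near-identical neighbour (chromosome 10, 118289629 to 118295038), which rose from 4.58 ± 1.41 to 24.6 ± 2.46 TPM; the log2 fold change of their sum was 2.42. In WT replicate 1, Il17a and Il24 were 0.56 and 0.65 log2 units below the other WT libraries, and without it their log2 fold changes were 1.47 and 1.49.

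**Figure D2:**
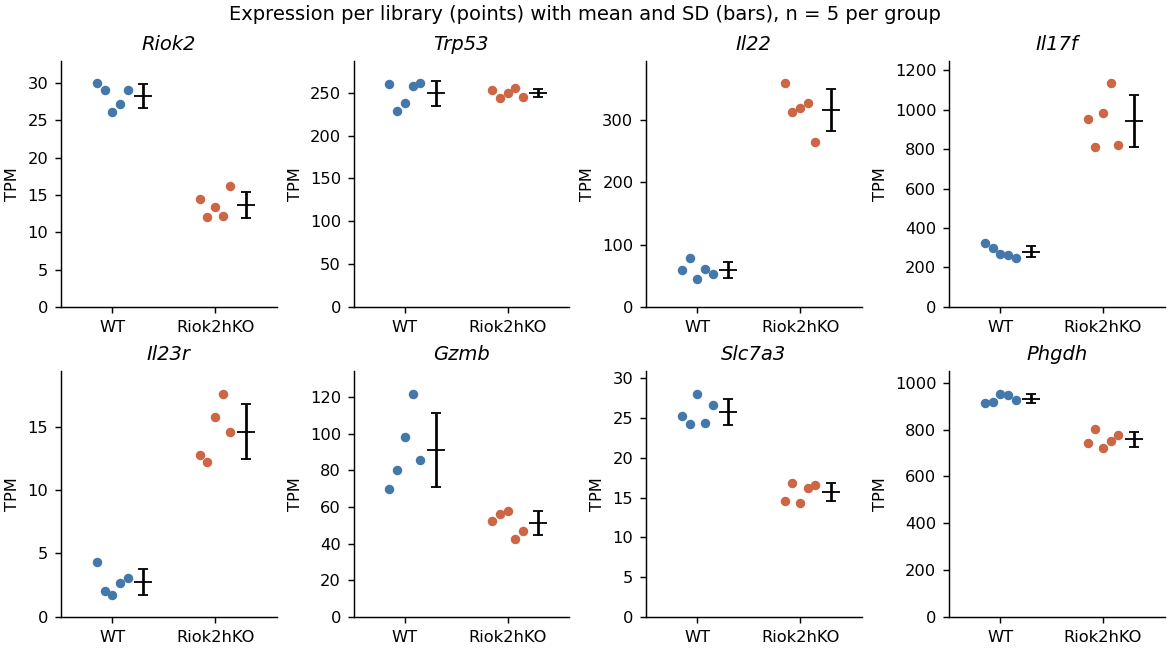
TPM of 8 genes in each library (points; WT in blue, Riok2hKO in orange), with the mean and SD of 5 libraries as bars; every vertical axis starts at 0. The groups do not overlap for Riok2, Il22, Il17f, Il23r, Gzmb, Slc7a3 and Phgdh, and they overlap for Trp53.

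In the list of chemokines and interleukins, 10 of 31 tested members rose and 4 fell (11 and 4 adjusted over the list alone). The median was 0.12 (camera adjusted p = 0.000411, adjusted p = 0.103 with an estimated correlation). The median was 0.073 without Riok2hKO replicate 1 and 0.082 without WT replicate 1. Lif rose from 25.1 ± 3.30 to 58.9 ± 4.49 TPM and Ltb, encoding lymphotoxin beta, from 168 ± 11.8 to 272 ± 9.42. In the list of T cell activation genes and co-receptors 9 of 27 rose and 4 fell (10 and 5 over the list alone; median 0.071, camera adjusted p = 0.0442, adjusted p = 0.452 with an estimated correlation), led by Tnfrsf8, which encodes CD30 and went from 32.5 ± 2.16 to 86.6 ± 9.59 TPM. That list lost its call without WT replicate 1 (adjusted p = 0.168), in which Dusp2 and Tnfsf11 were low, and without Riok2hKO replicate 1 (0.0553), 3 (0.0556) or 5 (0.0874). With any 1 library left out its median was 0.045 (without WT replicate 2) to 0.126 (without WT replicate 4). In those fits 6 to 10 of its genes rose, fewest without Riok2hKO replicate 5. Il2ra, which encodes the IL-2 receptor alpha chain, rose from 180 ± 5.77 to 302 ± 21.7 TPM within the regulatory T cell list, where 3 of 15 rose and 2 fell (3 and 3 over the list alone; camera adjusted p = 0.808).

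Others among the 10 largest increases were mostly genes of receptors and enzymes. Enpp2, which encodes the lysophosphatidic acid-producing enzyme autotaxin, went from 1.12 ± 0.795 to 9.06 ± 1.5 TPM, and Plac8 from 3.0 ± 0.982 to 15.9 ± 6.44. The leukotriene receptor gene Cysltr1 went from 5.57 ± 0.955 to 19.6 ± 2.89 TPM. The inhibitory receptor gene Lilrb4 went from 16.2 ± 2.48 to 62.4 ± 12.0 and its near-identical neighbour Gp49a from 6.13 ± 0.353 to 26.1 ± 5.10, and reads shared by this pair make the separate values uncertain.

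In the list of Th1 genes 5 of 18 rose and 6 fell (6 and 6 over the list alone). The list was not called as a group (median -0.037, camera adjusted p = 0.799). Its median was -0.109 without WT replicate 1 and 0.017 without WT replicate 2. Those that fell encode chemokines, cytotoxic granule proteins and Fas ligand: Xcl1 went from 30.0 ± 8.40 to 14.0 ± 5.36 TPM, Nkg7 from 53.4 ± 12.6 to 26.1 ± 3.49, Gzmb (granzyme B) from 91.2 ± 20.1 to 51.2 ± 6.33 and Fasl from 10.2 ± 0.961 to 5.90 ± 0.931, and Ccl3 and Ccl4 fell by 0.58 and 0.55 on the log2 scale. The receptor genes Il12rb2 (17.2 ± 1.45 to 40.1 ± 6.83 TPM) and Il18r1 (5.26 ± 0.797 to 9.07 ± 0.808) were among those that rose. Of the 3 tested genes of the CD8 and cytotoxic cell list, Cd8b1 fell by 0.48 on the log2 scale, and Prf1 (1.78 ± 0.818 and 1.01 ± 0.222 TPM, adjusted p = 0.117) and Klrc1 (1.39 ± 1.22 and 2.52 ± 0.833, adjusted p = 0.146) did not pass. Tbx21, which encodes the Th1 factor T-bet, measured 18.7 ± 1.05 and 17.4 ± 2.11 TPM (adjusted p = 0.355), and Ifng 2.12 ± 0.984 and 2.46 ± 2.35 (adjusted p = 0.975). Among inhibitory receptors 1 of 11 rose and 4 fell (3 and 4 over the list alone; camera adjusted p = 0.253): Pdcd1, encoding PD-1, went from 152 ± 5.30 to 119 ± 7.12 TPM and Lag3 from 80.0 ± 10.7 to 49.9 ± 7.82. No gene of that list rose without Riok2hKO replicate 1, 2, 3 or 4 or WT replicate 1 or 5.

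Genes of other T cell states were mixed. Of 10 Th2 genes, 4 rose and 1 fell (4 and 1 over the list alone). The median was 0.19 (camera adjusted p = 0.0273, adjusted p = 0.220 with an estimated correlation). Il9 went from 6.00 ± 2.68 to 16.98 ± 4.88 TPM, Ccr4 from 42.0 ± 1.17 to 58.3 ± 2.72 and Il4ra from 97.45 ± 3.01 to 133 ± 11.1. The 1 that fell was Gata3, which encodes the main Th2 transcription factor (31.4 ± 1.70 to 26.6 ± 2.52 TPM, adjusted p = 0.0277), and 0 fell without Riok2hKO replicate 2, 3 or 4 or WT replicate 2, 4 or 5. The Th2 call ended without WT replicate 1 (median 0.093, adjusted p = 0.0619) and without Riok2hKO replicate 1 (median 0.073, adjusted p = 0.0826). Of 18 naive T cell genes 7 rose, among them Satb1 (41.4 ± 2.01 to 56.0 ± 2.49 TPM) and S1pr1 (9.30 ± 0.941 to 16.1 ± 1.86), and 7 fell (8 and 8 over the list alone; camera adjusted p = 0.561). Of 6 tested target genes of the aryl hydrocarbon receptor 2 rose, Nqo1 and Tiparp (4 over the list alone). Nfe2l2 and Asb2 were higher but did not pass (log2 fold change 0.17 and 0.32, adjusted p = 0.0691 and 0.122). Cyp1a1 measured 1.54 ± 0.229 TPM in WT and 1.70 ± 0.661 in Riok2hKO (adjusted p = 0.850). Gstt1 measured 6.97 ± 1.04 and 6.55 ± 0.799 (adjusted p = 0.649). The list median was 0.24 (camera adjusted p = 0.0390, adjusted p = 0.220 with an estimated correlation, and 0.0854 without WT replicate 1). The list lost its call also without Riok2hKO replicate 1 (0.0504) or 3 (0.0560), and Tiparp lost its own without Riok2hKO replicate 3, 4 or 5 or WT replicate 1, 2 or 5 (adjusted p = 0.0648 to 0.0994). Just 1 target rose without Riok2hKO replicate 3, 4 or 5 or WT replicate 1 or 5.

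The integrated stress response includes the amino acid-responsive programme downstream of the transcription factor ATF4. Of 37 tested members of its list 25 fell, 0 rose and 12 did not pass (30 fell over the list alone). The median log2 fold change was -0.16 (camera adjusted p = 1.65e-14, adjusted p = 0.103 with an estimated correlation). The arginine and lysine transporter gene Slc7a3 went from 25.8 ± 1.61 to 15.7 ± 1.17 TPM and Chac1, a glutathione-degrading enzyme, from 18.1 ± 1.89 to 9.71 ± 2.81. The stress factor genes Ddit3 and Trib3 fell by 0.58 and 0.67 on the log2 scale. Enzymes of serine and asparagine synthesis fell by less: Phgdh from 932 ± 18.5 to 759 ± 31.6 TPM, Psph from 172 ± 3.91 to 141 ± 5.75 and Asns from 192 ± 12.9 to 147 ± 8.10. Without WT replicate 1 the list held 24 members that fell, with a median of -0.15.

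In the unfolded protein response list 9 of 22 members rose, 1 (Herpud1) fell and 12 did not pass (14 and 1 over the list alone). The median was 0.15 (camera adjusted p = 1.17e-05, adjusted p = 0.103 with an estimated correlation). Hyou1 went from 17.8 ± 1.2 to 23.9 ± 1.54 TPM, Calr from 345 ± 11.5 to 406 ± 11.1, Sdf2l1 from 173 ± 4.27 to 204 ± 6.66 and Hsp90b1 from 359 ± 13.3 to 405 ± 10.4. The count of members that fell was 0 without Riok2hKO replicate 1, 2 or 3 or WT replicate 2.

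In the glycolysis list 13 of 27 tested members rose, 0 fell and 14 did not pass (17 and 2 over the list alone). The median was 0.10 (camera adjusted p = 1.62e-05, adjusted p = 0.422 with an estimated correlation). Hk2, encoding hexokinase 2, went from 36.2 ± 0.503 to 48.1 ± 2.12 TPM, the mitophagy receptor gene Bnip3 from 117 ± 5.83 to 171 ± 17.4, Egln3, an oxygen sensor, from 70.4 ± 3.50 to 105 ± 12.7, and the glucose transporter gene Slc2a1 from 76.6 ± 2.90 to 88.5 ± 3.10. Egln3 and Bnip3, which do not encode glycolytic enzymes, had the largest log2 fold changes of the list (0.56 and 0.54). Among abundant enzyme genes, Pkm, Pgk1 and Eno1 rose by 0.13, 0.11 and 0.10 on the log2 scale. Aldoa, Gapdh and Ldha did not pass (0.0042, 0.083 and -0.049).

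Of 32 small subunit ribosomal protein genes 1 rose and 10 fell (2 and 12 over the list alone; median -0.024, camera adjusted p = 0.00943, adjusted p = 0.422 with an estimated correlation), among them Rps18 (5365 ± 95.4 to 4973 ± 63.7 TPM). None rose without Riok2hKO replicate 1, 3 or 4 or WT replicate 4 or 5, and 2 rose without WT replicate 1 or 2. The small subunit median was 0.0050 after a trend on GC content and length was removed, and the call was lost with quantile normalization (adjusted p = 0.346). Of 47 large subunit ribosomal protein genes 5 rose and 14 fell (6 and 16 over the list alone; median -0.026, camera adjusted p = 0.0272, adjusted p = 0.469 with an estimated correlation), with Rpl3 falling from 3991 ± 57.9 to 3658 ± 30.1 TPM and Rpl22 rising from 221 ± 7.39 to 246 ± 5.71. The large subunit call was lost with quantile normalization (adjusted p = 0.837) and without Riok2hKO replicate 5 (adjusted p = 0.123), WT replicate 2 (0.0767) or WT replicate 3 (0.0581). Without Riok2hKO replicate 5 its median was -0.014. Without Riok2hKO replicate 1, 3 or 4 or WT replicate 5, 2 of its genes rose. For comparison, the median log2 fold change was -0.006 over all tested genes and -0.017 over genes with a mean of at least 10 TPM.

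Factors that assemble the subunits were mostly not called. Of 53 small subunit assembly factors 1 rose and 2 fell (0 over the list alone; camera adjusted p = 0.253), Utp18 upwards and Nol11 and Tbl3 downwards. Without WT replicate 1, 4 rose, among them the fibrillarin gene Fbl (adjusted p = 0.000186), and 2 fell. Nol11 lost its call without Riok2hKO replicate 3 or 4 (adjusted p = 0.0519 and 0.0522) and Tbl3 without Riok2hKO replicate 1, 3 or 4 or WT replicate 5 (0.0521 to 0.0588). The count that fell was 0 without Riok2hKO replicate 4, 1 without Riok2hKO replicate 1 or WT replicate 5, and 4 without WT replicate 3. Pno1, whose product acts beside RIOK2 in late maturation, measured 228 ± 11.4 and 210 ± 8.12 TPM (adjusted p = 0.0515). Of 49 large subunit factors 4 rose (Zfp622, Ddx51, Pelp1 and Senp3) and 2 fell (3 and 0 over the list alone; camera adjusted p = 0.658), against 6 and 1 without WT replicate 1. None fell without Riok2hKO replicate 1, 2, 3 or 4 or WT replicate 4 or 5, 1 fell without WT replicate 2 and 4 fell without Riok2hKO replicate 5. Pelp1 lost its call without Riok2hKO replicate 2, 3, 4 or 5 or WT replicate 2, 4 or 5 (adjusted p = 0.0616 to 0.0872). Utp18 and Zfp622 had their lowest values in WT replicate 1, 7.30 TPM against 18.2 to 24.5 in the other WT libraries and 3.11 against 6.80 to 8.36. Fbl was low there too (108 TPM against a mean of 258). Without that library 81 of the 122 genes at least 1 log2 unit low in it were called higher, so such calls are not particular to assembly factors. Among translation factors 8 of 44 rose and 11 fell (8 and 16 over the list alone; camera adjusted p = 0.128). Eif4g2 went from 187 ± 10.0 to 223 ± 10.8 TPM and Eif2b5 from 30.0 ± 3.14 to 40.8 ± 3.23, while Eef1g fell from 2367 ± 45.9 to 2201 ± 32.8.

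Trp53 mRNA measured 249 ± 14.8 TPM in WT and 249.7 ± 5.10 in Riok2hKO (log2 fold change 0.0052, 95% interval -0.079 to 0.089, exact permutation p = 0.897). Of 35 tested p53 target genes 10 rose, 4 fell and 21 did not pass (11 and 5 over the list alone). The list median was 0.10 (camera adjusted p = 0.0385, adjusted p = 0.337 with an estimated correlation). Phlda3 (20.5 ± 6.47 to 41.1 ± 3.48 TPM) and Plk3 (13.9 ± 3.76 to 26.9 ± 4.15) rose most. Cdkn1a, the p21 gene, and Mdm2 rose by 0.25 and 0.13 on the log2 scale, and Btg2 (37.0 ± 2.11 to 30.0 ± 0.838 TPM) and Sesn1 (14.0 ± 1.63 to 10.3 ± 1.01) fell. Phlda3, Plk3, Dyrk3 and Ddit4, 4 of the 10 that rose, were 0.83 to 1.28 log2 units lower in WT replicate 1 than in the other WT libraries. Each was still called without that library. So were 81 of the 122 genes at least 1 log2 unit low there, all of these upwards in Riok2hKO. Keeping the call therefore does not set these 4 apart from other genes low in WT replicate 1. The list lost its call without the genes at least 0.5 log2 units low in WT replicate 1 (31 members tested, median 0.074, adjusted p = 0.144), and without Riok2hKO replicate 1 (adjusted p = 0.105), Riok2hKO replicate 3 (0.0525), WT replicate 3 (0.0610) or WT replicate 4 (0.0685). In the apoptosis list 6 of 30 members rose and 5 fell (7 and 6 over the list alone; camera adjusted p = 0.497). With any 1 library left out 6 to 7 rose and 1 to 4 fell, the fewest falling without Riok2hKO replicate 1, 2, 3 or 4 or WT replicate 2 or 5. Casp6 went from 42.9 ± 2.32 to 84.8 ± 9.70 TPM and Bak1 from 9.46 ± 1.46 to 13.6 ± 0.847. In the DNA damage list 0 of 30 rose and 1, Xrcc6, fell (0 over the list alone; camera adjusted p = 0.606); its call was lost without any 1 of 8 of the 10 libraries (Riok2hKO replicates 1 to 4 and WT replicates 1, 2, 3 and 5; adjusted p = 0.0533 to 0.0756).

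Of 49 G2/M genes 13 rose, 0 fell and 36 did not pass (17 over the list alone; median 0.082, camera adjusted p = 8.08e-05, adjusted p = 0.422 with an estimated correlation), with Top2a going from 108 ± 5.79 to 134 ± 6.51 TPM. Of 42 S phase genes 2 rose and 4 fell (2 and 3 over the list alone; median -0.049, camera adjusted p = 0.0442, adjusted p = 0.657 with an estimated correlation, and 0.215 without WT replicate 1), and the call was lost also without Riok2hKO replicate 1 (0.0887), 3 (0.0707) or 4 (0.0995). With 1 library left out 1 to 4 S phase genes fell, fewest without Riok2hKO replicate 3 or 4 or WT replicate 5, and 1 to 3 rose, most without WT replicate 1. Of 29 replication-dependent histone genes 5 rose (5 over the list alone; median 0.15, camera adjusted p = 0.0407, adjusted p = 0.309 with an estimated correlation, and 0.0854 without WT replicate 1), led by Hist2h3c2 (110 ± 5.62 to 153 ± 7.86 TPM). The histone call was lost also without Riok2hKO replicate 2 (0.104) or 3 (0.0647, median 0.076) or WT replicate 2 (0.0510), 4 (0.0524) or 5 (0.0610). Leaving out 1 library gave 2 to 5 histone genes that rose, fewest without Riok2hKO replicate 4 or WT replicate 2 or 4.

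**Figure D3:**
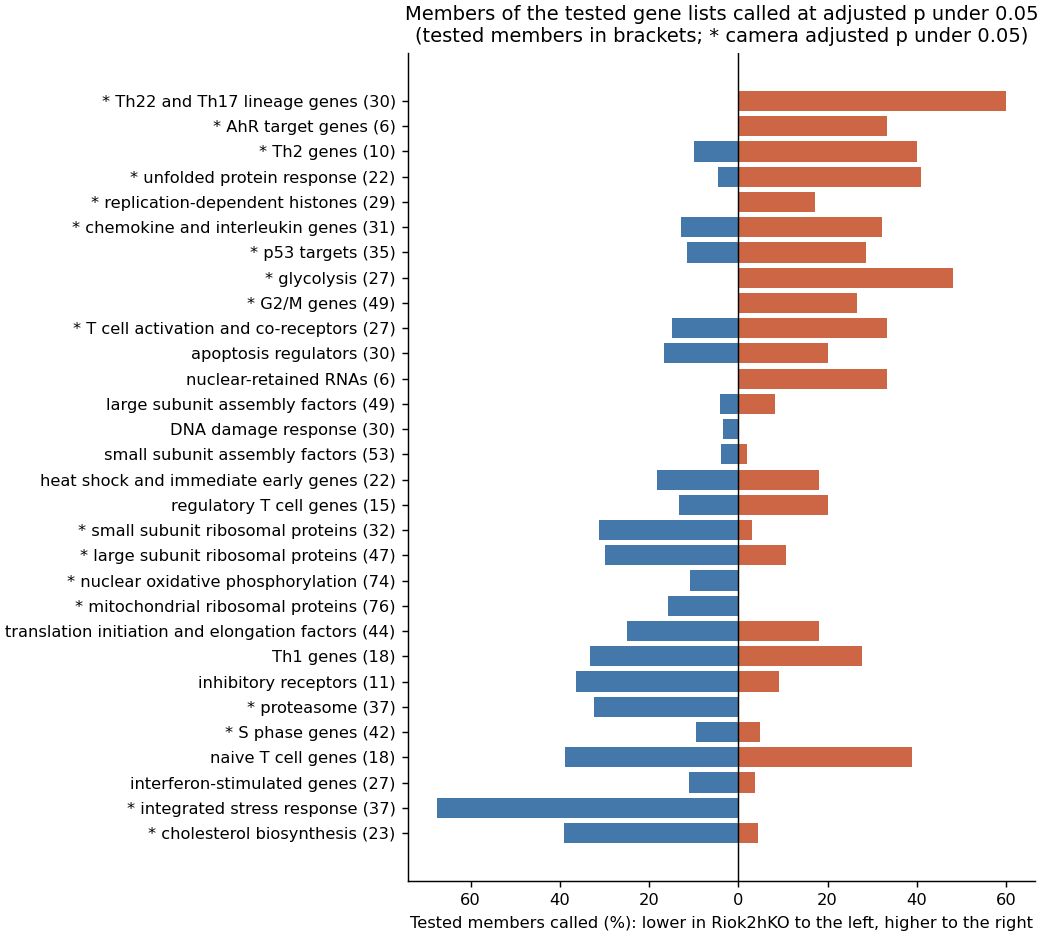
Share of the tested members of 30 gene lists that fell (blue, to the left) or rose (orange, to the right) in Riok2hKO, as a percent of the tested members, which are given in brackets. The lists run from the highest median log2 fold change at the top to the lowest at the bottom; an asterisk marks the 18 with a camera adjusted p under 0.05, of which 1, the Th22 and Th17 list, held with an estimated correlation.

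Some list calls rested on few members or small shifts. Counting every alternative setting that gave the list a value, the S phase call was lost in 13 of 28, T cell activation in 10 of 28, histones in 9 of 28, p53 targets in 8 of 28, large subunit ribosomal proteins in 11 of 27, aryl hydrocarbon receptor targets in 7 of 27, nuclear oxidative phosphorylation in 7 of 28, mitochondrial ribosomal proteins in 2 of 28, Th2 genes in 4 of 28 and small subunit ribosomal proteins in 4 of 27. The calls for the integrated stress response, unfolded protein response, glycolysis, G2/M, cholesterol, proteasome and chemokine lists were lost in 1 of 28, the estimated correlation, and that for the Th22 and Th17 list in 0 of 28. Leaving out 1 library also changed how many members passed: 4 to 16 G2/M genes rose (fewest without WT replicate 3), 5 to 11 p53 targets (fewest without Riok2hKO replicate 3) and 8 to 14 glycolysis genes (fewest without Riok2hKO replicate 4), and 4 to 10 translation factors fell (fewest without Riok2hKO replicate 1). In the same fits 16 to 18 Th22 and Th17 genes rose and 20 to 24 integrated stress response genes fell.

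Most markers of other cells were near the floor in both groups. Among 16 measured B cell genes, 11 stayed under 1 TPM in every library, as did 20 of 23 myeloid genes, 11 of 14 erythroid and platelet genes, 8 of 13 CD8 and cytotoxic genes and 5 of 9 genes of innate lymphoid and gamma delta T cells. The most abundant exceptions in the B cell and myeloid lists were Ctss (63.9 ± 7.57 and 58.9 ± 2.23 TPM in WT and Riok2hKO, adjusted p = 0.305), H2-Ab1 (34.1 ± 4.46 and 42.7 ± 8.07, adjusted p = 0.0893) and Cd74 (16.1 ± 2.20 and 12.4 ± 2.76, adjusted p = 0.0731). Others were Cd8b1, which fell from 18.02 ± 1.00 to 12.7 ± 1.5 TPM while Cd8a measured 0.26 ± 0.131 and 0.18 ± 0.107, and Id2, a gene that T cells also express, which rose from 91.2 ± 8.91 to 153 ± 8.26. Ebf1 rose from 2.53 ± 0.358 to 3.69 ± 0.469 TPM. Tfrc, which dividing T cells express, rose from 186 ± 12.4 to 211 ± 12.1 TPM, a call lost without Riok2hKO replicate 3, 4 or 5 or WT replicate 2 or 4 (adjusted p = 0.0626 to 0.0701). The female-specific transcript Xist, overlapped by Tsix, measured 46.0 ± 0.345 TPM in WT and 46.0 ± 0.844 in Riok2hKO.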

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

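Tests chosen only after the result was seen were the sum of Il22 and Iltifb, the search for other lineages and for IL-22-negative cells among the WT Th22 cells, the T cell genes of WT replicate 1, the comparison of WT replicate 1 with the genotype difference, and the alternatives without genes low in WT replicate 1 and with a GC and length trend removed; the search for GC-rich stretches followed from the weak relation with whole-transcript GC content, and the error allowed around its bound for genes higher in Riok2hKO was added after that share was known. A library was singled out where its gap to the nearest library of its group was over 0.71 of the group's range, which chance does in about 1 group in 20. Of 360 groups of 5 values 25 passed (6.94%), 14 of them for WT replicate 1 and 11 for another library.

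WT replicate 1 stood out on the first and second principal components (gap over range 0.890 and 0.772) and was the lowest WT library for Phlda3 (9.03 TPM, the others 22.0 to 24.2; 0.904), Plk3 (7.29, the others 14.5 to 16.1; 0.864), Zfp622 (3.11, the others 6.80 to 8.36; 0.779), Utp18 (7.30, the others 18.2 to 24.5; 0.745), Hyou1 (15.6, the others 17.97 to 18.6; 0.793) and Eif4g2 (169, the others 188 to 194; 0.786). It was the highest for Casp8ap2 (8.15, the others 6.83 to 7.04; 0.830), Cenpf (6.24, the others 5.22 to 5.40; 0.812) and Hist2h3c2 (120 against 107 to 109; 0.814). Its mean log2 value was low for T cell activation genes (6.21 against 6.51 to 6.56; 0.833) and small subunit ribosomal proteins (11.62 against 11.64 to 11.65; 0.774) and high for S phase genes (6.17 against 6.08 to 6.10; 0.741). The 2 low means include Dusp2 and Tnfsf11 (deviations of -2.72 and -2.36 log2 units) and Rps2 (-1.48), so they need not reflect a shift of the whole list.

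In that library 122 genes were at least 1 log2 unit lower than in the other WT libraries. Dilution by cells of another lineage would need at least as much RNA from them as from T cells and would lower T cell genes as much. Of 14 such genes, among them Cd3e and Cd4, the median deviation was 0.027 (quartiles -0.025 and 0.039), which argues against this cause but not against a small share of such cells. Transcripts with a GC-rich stretch were over-represented: the median highest GC share of any 100-nucleotide window was 81% in the low genes against 72% in lists matched on expression, at percentile 100 of 10000 lists, while whole-transcript GC content had a Spearman rho of -0.125 and length one of -0.076 with the deviation across genes, too weak to settle those 2. A loss of GC-rich templates in reverse transcription or amplification of this library is therefore a candidate cause, and the labels give no batch to set it against. A larger distance along the genotype difference stays open too, because the deviation, taken against a pair of the other WT libraries, had a mean Pearson r of -0.184 across genes (range -0.216 to -0.158 over 6 halvings) with the genotype effect measured against the remaining pair; without WT replicate 1, 81 of the 122 low genes were called higher in Riok2hKO and 2 lower. Among genes with no window of 70% GC or more, 7.59% were called higher and 8.44% lower without WT replicate 1, against 11.5% and 6.18% of genes with such a window and 10.0% higher of all genes. The excess of increases over decreases thus lay in genes with such a window (726 up and 390 down, against 296 and 329 without one). GC-rich stretches may therefore have added to the increases of such genes in Riok2hKO. The test itself decided nothing, because the share lay within its error of the bound of 0.75 times that of all genes. How many increases came from such stretches cannot be told apart from genotype, as the labels give no batch.

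The higher Th22 and Th17 genes in Riok2hKO included Il22. Reads moved from Iltifb are argued against as its cause, since Iltifb held 4.58 TPM in WT and itself rose to 24.6 in Riok2hKO. The summed TPM of both had a log2 fold change of 2.42 (95% interval 2.14 to 2.70), which follows from those values and is no separate evidence. Cells of another lineage in the WT sort are also argued against: 1 of 7 lineage markers (Cd8b1) reached a WT mean of 1 TPM, the other 6 stayed at or under 0.48 in every library, and the most abundant B cell and myeloid markers, Ctss and H2-Ab1, measured 63.9 and 34.1 TPM in WT against 58.9 and 42.7. IL-22-negative CD4+ T cells passing the gate in WT could dilute Il22, and would then lower no other transcript by a larger ratio. Of 7784 genes with a mean of at least 5 TPM, 0 had a TPM ratio with a lower 95% bound above the upper bound of Il22 (ratio 5.34, 4.11 to 6.95), although the ratios of Enpp2 (8.06, 3.38 to 19.2) and the gene model Gm10052 (8.69, 1.14 to 66.2) were higher. Dilution and higher expression per cell therefore cannot be told apart within these errors, and a change of T cell state with genotype stays open as a hypothesis.

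The lower integrated stress response genes did not rest on WT replicate 1, without which the list median was -0.152, nor on a trend with GC content and transcript length, after whose removal it was also -0.152. These checks do not separate an effect of genotype from a difference between cultures. A biological difference between the genotypes, with a lower ATF4 programme in Riok2hKO, stays a hypothesis found and tested on these libraries. A difference between cultures in amino acid supply or cell density was not tested, since the labels do not say how the libraries map to cultures. WT replicate 3 was highest in the list mean (6.03 against 5.95 to 5.97; gap over range 0.767), and the call was lost with an estimated correlation (adjusted p = 0.103).

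Other libraries stood out in single measures. WT replicate 3 was low in the unfolded protein response mean (6.15 against 6.17 to 6.19; 0.711) and in the nuclear-retained RNA mean (3.75 against 3.85 to 3.86; 0.861). WT replicate 4 was high for Il12rb2 (19.7 TPM against 16.2 to 16.7; 0.831) and Il7r (8.57 against 6.15 to 6.77; 0.715), and WT replicate 2 was low for Prim1 (101.0 against 113.5 to 118.8; 0.717) and Eef1g (2288 against 2368 to 2400; 0.726). Riok2hKO replicate 1 was low for Pelp1 (19.4 against 21.0 to 21.5; 0.791) and Mrpl38 (81.1 against 88.4 to 90.1; 0.825), replicate 2 high for Ccr4 (63.0 against 56.0 to 57.7; 0.751) and replicate 5 low for Hist2h3c2 (139 against 155 to 158; 0.843).

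Of 100 splits of the 10 libraries into 5 and 5, drawn from the 126 possible, 1 gave 1770 genes or more. That was the genotype split itself, and the highest other split gave 1. The count of changed genes thus followed the genotype labels of these libraries. A chance difference between mice or cultures cannot be excluded this way, since the labels do not say whether libraries of a group came from separate ones. In mixed splits the genotype difference also widens the spread within groups, which lowers their calls. For lists, 1 of the 100 splits gave 18 camera calls or more, again the genotype split, but the highest other split gave 16, the median of the others was 6, and 98 of the 99 others called at least 1 list. Every other split keeps part of the genotype difference: the 20 that exchanged 1 library per side called 6 to 16 lists and the 79 that exchanged 2 called 0 to 14.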

How the results depend on the processing

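The fits with a GC and length trend removed, with genes low in WT replicate 1 left out, with date rows kept and with Il22 and Iltifb summed were chosen after seeing the data. In every alternative Riok2 stayed lower (log2 fold change -1.06 to -0.84) and Il22 higher (2.32 to 2.52), each past the threshold, and 97 of the 126 changed genes under the naming rule kept direction and call wherever they were tested. The number of changed genes was 1199 (without Riok2hKO replicate 4) to 1852 (array weights), except for 2496 at an adjusted p under 0.1, 821 (476 up, 345 down; 782 of them among the 1770) with detected genes as a covariate, and 53 (48 up, 5 down) with a log2 fold change of at least 1, where the threshold itself differs for the first and last. Leaving out 1 library gave 1199 to 1749 genes and 12 to 17 lists. The share of calls that were upward was 55.9% as reported and 47.2% (quantile normalization) to 60.9% (replicate block) in other fits at that threshold. Lists called by camera numbered 12 to 20, except 1 with an estimated correlation. The p53 target median (0.10, adjusted p = 0.0385) lost its call with an estimated correlation (0.1046, adjusted p = 0.337), at a mean of at least 10 TPM (0.0755, adjusted p = 0.0849), with detected genes as a covariate (0.1006, adjusted p = 0.0957) and without genes low in WT replicate 1 (0.074, adjusted p = 0.144); leaving out 1 library gave 0.088 to 0.127 (adjusted p = 0.0137 to 0.105). The small subunit ribosomal protein median turned from -0.024 to 0.0050 (adjusted p = 0.756) with the GC and length trend removed. The cause was not tested for these. Libraries with the same replicate number shared little deviation (r across genes -0.034 to 0.068, the highest with its own number for 1 of 5). These correlations cannot exclude pairing, on which the labels are silent. A replicate block gave 1444 genes (880 up, 564 down), 1332 of them among the 1770. Rescaling without mitochondrially encoded genes was not run, as 0 of 26 were among the symbols used here. Depth is unknown, so what it limits cannot be stated.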

Other observations

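No test in this part was chosen after its result was seen, except that Srebf2 was picked after its value was known. Leaving out 1 library moved several counts given here (5 to 14 cholesterol genes fell, fewest without Riok2hKO replicate 3; 6 to 10 proteasome genes fell, fewest without Riok2hKO replicate 4 or WT replicate 3; 6 to 10 mitochondrial ribosomal protein genes fell, fewest without WT replicate 5; 0 cholesterol genes rose without Riok2hKO replicate 1, 3 or 5 or WT replicate 3, 4 or 5). Of 23 cholesterol synthesis genes 9 fell, 1 rose and 13 did not pass (15 and 1 adjusted over the list alone). The median was -0.16 (camera adjusted p = 0.000137, adjusted p = 0.422 with an estimated correlation). Hmgcs1, at the entry of the pathway, went from 126 ± 13.9 to 98.8 ± 5.34 TPM (mean ± SD of 5 libraries), Idi1 from 149 ± 5.12 to 122 ± 12.5 and Cyp51 from 86.8 ± 1.81 to 74.8 ± 2.94, while the 1 that rose was Srebf2, whose product activates these genes (46.1 ± 2.11 to 53.2 ± 4.65). Of 37 proteasome genes 12 fell, 0 rose and 25 did not pass (12 over the list alone, and 7 and 0 over all genes without WT replicate 1; median -0.048, camera adjusted p = 2.66e-05, adjusted p = 0.220 with an estimated correlation), for example Psmb6 from 649 ± 9.61 to 589 ± 10.0 TPM.

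Of 76 mitochondrial ribosomal protein genes 12 fell, 0 rose and 64 did not pass (16 over the list alone; median -0.035, camera adjusted p = 0.000827, adjusted p = 0.452 with an estimated correlation), or 7 and 1 without WT replicate 1 (median -0.022), with Mrpl55 going from 102 ± 2.20 to 91.3 ± 2.59 TPM. Of 74 nuclear genes of oxidative phosphorylation 8 fell, 0 rose and 66 did not pass (7 over the list alone; median -0.029, camera adjusted p = 0.00943, adjusted p = 0.484 with an estimated correlation, and 0.0897 without WT replicate 1, where 4 fell, 2 rose and the median was -0.014), with Uqcrc1 going from 642 ± 12.7 to 564 ± 4.97 TPM. Interferon-stimulated genes (1 of 27 rose and 3 fell, likewise over the list alone; camera adjusted p = 0.145) and heat shock and immediate early genes (4 of 22 rose and 4 fell, 5 and 5 over the list alone; camera adjusted p = 0.987) were not called. Without Riok2hKO replicate 3, 1 of the interferon-stimulated genes fell, and without Riok2hKO replicate 4 or 5 or WT replicate 5, 2 of the heat shock list fell. Of the oxidative phosphorylation genes 4 fell without Riok2hKO replicate 3 and 5 without Riok2hKO replicate 4 or WT replicate 2. The small list medians stand beside a median log2 fold change of -0.006 for all tested genes. Among genes with a mean of at least 10 TPM that median was -0.017. Of 6 nuclear-retained RNAs Malat1 (85.8 ± 2.56 to 108 ± 1.94 TPM) and Neat1 rose (2 over the list alone; camera adjusted p = 0.264). Neat1 lost its call without Riok2hKO replicate 1, 4 or 5 or WT replicate 4 or 5 (adjusted p = 0.0533 to 0.0699).

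Genes near Riok2 on chromosome 17 could differ if the targeted allele carried flanking sequence of another strain. Within 10 Mb of Riok2, 25 of 157 tested genes (15.9%, Riok2 left out) changed, against 1743 of 10132 elsewhere (17.2%; Fisher's exact test, two-sided, p = 0.7495), which argues against such an excess.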
